A study of Bos taurus with 9 samples.

How the data were processed

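Granulosa cells, the follicle layer that makes oestradiol from thecal androgen, came from dominant (preovulatory) follicles of Holstein-Friesian cows. Per the labels they were taken by ovum pick-up 42 hours after a prostaglandin injection, at 30, 60, 90 and 120 days after calving. The cells were spun out of the follicular fluid and washed in buffer, and no sort of cell types is given in the sources used here. RNA was amplified by 2 rounds of T7 transcription, labelled chemically on guanine and hybridised to a bovine EMBV3 array on an Agilent slide. Each of 9 arrays carried RNA of 30, 60 or 90 days in Cy5, with 3 arrays per day, and 120-day RNA in Cy3. No array had the dyes exchanged, so a dye effect of a probe stays in each ratio against 120 days and cancels between days when it is the same on all arrays.

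The deposited array files give, for each spot, the mean and the median pixel intensity and the local background in both channels, not background-subtracted and not normalised. The scanner and its software are not given in the sources used here. The authors' value table holds log2 values per probe, and how they were made is not given in the sources used here. The columns of that table were compared with the array files, did not match the ratios of their own arrays, and were not used further. The array files were taken as named, so each comparison of days rests on those names. The trimmed mean columns were not used, since the mean and the median of the same spots were.

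Each array file held 45220 spots, after 14 summary lines at its end had been dropped, among them 43794 probes with 1 spot each, 153 negative control spots and 8 spots with no identifier. Mean intensities were background-corrected with normexp (offset 50) and normalised within each array by loess, with control spots given no weight, in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table). Probes were kept when the mean signal of either channel exceeded the mean of the negative control spots by 2 SD on at least 3 arrays, which left 38823 probes (88.6%). A table of gene symbols per probe gave 1 symbol for 21790 probes and none for the other 22004. The tested probes covered 14281 genes, each represented by its probe with the highest mean brightness (A) over all arrays. Older symbols in the gene lists were matched through the names and synonyms of a RefSeq gene table of assembly ARS-UCD2.0. No coordinates were used.

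One limma model (lmFit and eBayes) was fitted to all 9 arrays, with 1 coefficient per day. It had 6 residual and 1.36 prior degrees of freedom. Each day was tested against 120 days, each pair of days was contrasted, and an F test asked for any difference among 30, 60 and 90 days. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Errors are the model's standard errors (SE), and n is 3 arrays per day. The number of arrays limits the precision. By the correlation of their Cy3 signals, each day's 3 arrays appeared to carry 3 different 120-day RNAs. The spread behind a ratio then includes that between the 120-day RNAs. The comparisons with 120 days share those RNAs and are not independent of each other.

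For 35 lists of pathway and cell type genes, 34 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of mitochondrially encoded genes had 0 measured members. Lists, comparisons, tests and the alternatives listed first were chosen before the data were examined. List tests of 30 against 60 days and of 60 against 90 days were added later. Genes were named by a rule: among genes past the threshold with the same sign on all 3 arrays of the day, the 10 highest and the 10 lowest changes. Where fewer than 5 passed in a direction, the 5 smallest p-values were taken. Up to 4 members of each list described were added, with the 2 brightest members of each cell type list. STAR, CYP11A1, CYP19A1, HSD3B1, FSHR, LHCGR, INHBA, IGF1 and VEGFA were always named. A symbol that names a microRNA, MIR147, met the rule at 60 days. Its probe cannot tell the microRNA from its host transcript, so no value is given.

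The alternatives were no background correction, median centring without loess, Aquantile between arrays, no filter on dim probes, the replicate number as a block, array weights, eBayes with trend and robust settings, only the arrays compared, unadjusted p with a 1.5-fold change, probes averaged per gene and leaving out each array. For lists, camera with an estimated correlation and fry, a rotation test, were also run. Chosen after the data had been seen were the 120-day RNA as a block, the granulosa marker median of each array as a covariate, a filter from the median and MAD of the control spots, median pixel signals, and a fit without the 3 arrays whose macrophage marker median lay above 1. Against 120 days, the 120-day RNA as a block takes the spread between those RNAs out of the error. Its calls there hold for those RNAs alone and can be too many. A fit with slide or array position as a block was not run, since 0 such fields are in the array files, and a fit to the authors' table was not run for the reason above.

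The steps were tested on simulated normal noise with the residual SD of each probe on the real arrays, with 200 of 38823 probes changed. The noise was independent between probes and between arrays, so it held no shared 120-day RNA. For 60 against 120 days, 55% of the probes changed by log2 1 and 71% of those changed by log2 2 were recovered, with 6 false calls. For 30 against 90 days these shares were 41% and 69%, again with 6 false calls. In a simulation of 60 against 120 days over 14281 genes, camera called the 1 list that had been shifted and 0 of the others. Its noise was independent between genes too, so this does not test camera on lists of correlated genes.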

Results

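Arrays with 2 colours measured the RNA of granulosa cells at 30, 60 and 90 days after calving, on 3 arrays per day, each against 120-day RNA in the other channel. The labels name 120 days as the reference and follicles before ovulation as the tissue, so each ratio asks how the granulosa cells of a given day differed from those at 120 days. Median spot signals ran from 127.5 to 450.3 in Cy5 and from 239.6 to 529.7 in Cy3, against median local backgrounds of 37.88 to 121.9 and 20.27 to 28.95. The share of probes above the negative control spots ran from 29.8% (30 days replicate 1) to 82.3% in Cy5. In Cy3 it ran from 20.9% to 84.2%. The lowest Cy3 share belonged to 60 days replicate 3, whose control spots put its threshold at 800.2, so a 120-day spot was often counted as dim on that array alone.

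Clustered by their correlation and cut at 3 groups, the 120-day channels fell into 3 sets of 3 arrays, and each set held 1 array of every day. Pearson r over probes ran from 0.9226 to 0.9847 within sets and from 0.723 to 0.9085 between sets. That a set shares 1 RNA is inferred from these signals. Set A held replicate 1 of 30 and 60 days and replicate 2 of 90 days, set B held replicate 2 of 30 and 60 days and replicate 1 of 90 days, and set C held replicate 3 of each day. The labels give 3 biological replicates for each time point. Arrays are named here as their files are, and whether replicates 1 and 2 of 90 days were exchanged in name is not known. Such an exchange would leave the comparisons of days as they are.

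**Figure D1:**
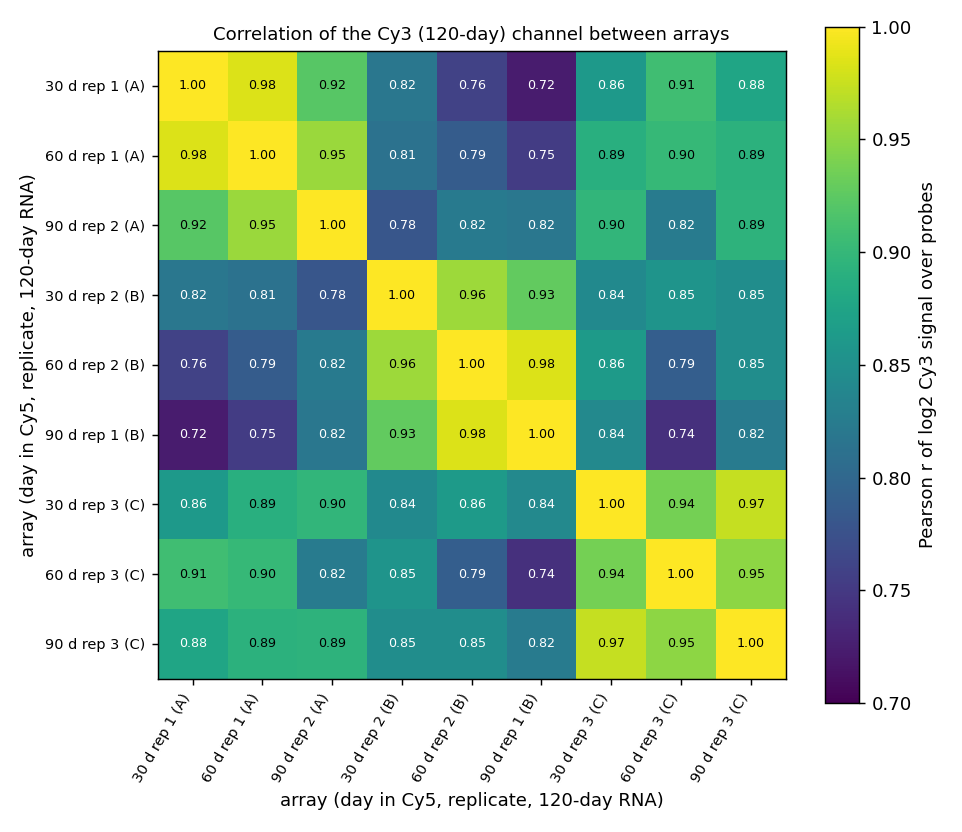
Pearson correlation, across probes, of the log2 Cy3 signal between each pair of the 9 arrays, ordered by the 120-day RNA set (A, B or C) of each array. The 3 blocks on the diagonal, 1 per set, hold the highest values. Probes are not independent replicates.

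Markers of cell types differed between arrays of the same day. The median log2 ratio of 13 granulosa cell markers was 0.44, -1.67 and -0.64 on replicates 1, 2 and 3 of 30 days, 0.64, 1.05 and 0.87 at 60 days, and -1.35, 0.36 and 0.15 at 90 days. That of 15 macrophage and monocyte markers was -1.47, 2.46 and 1.86 at 30 days, -1.01, -0.17 and -0.47 at 60 days, and 2.32, 0.54 and 0.26 at 90 days. The medians of 18 lymphocyte markers were -0.78, 0.69 and 0.08, then -1.60, -1.02 and -1.30, then 1.44, -0.58 and -0.36 in the same order. For 18 epithelial markers they were -0.13, -1.47 and -0.34, then -0.21, -1.81 and -0.32, then -1.26, -0.05 and -0.49.

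**Figure D2:**
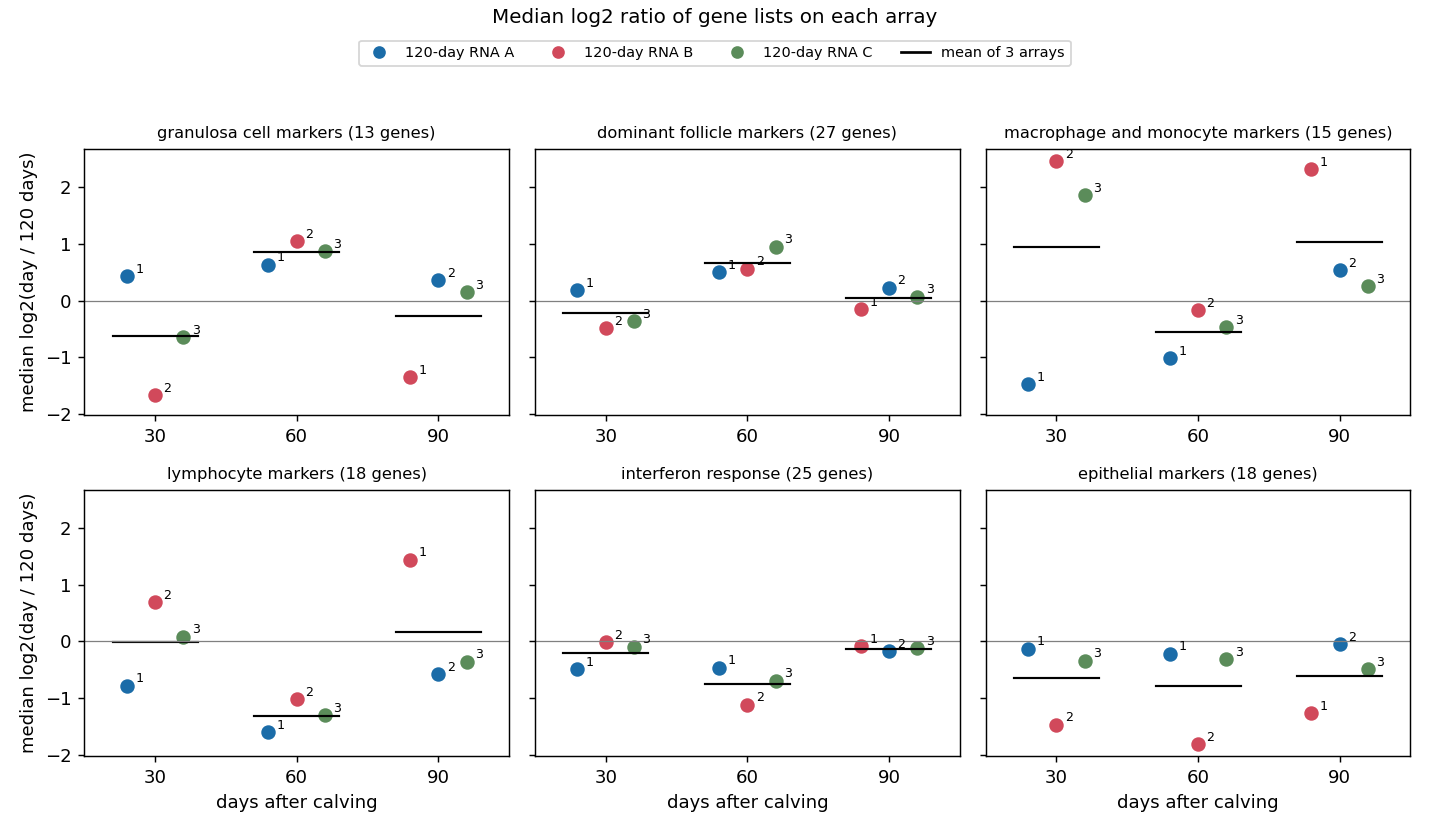
Median log2 ratio of the day over 120 days for 6 gene lists on each of the 9 arrays, with the replicate number beside each point, the 120-day RNA set as its colour and the mean of the day's 3 arrays as a bar. At 60 days all 3 arrays lay above 0 for granulosa markers (0.64, 1.05 and 0.87), while 30 and 90 days were spread on both sides of 0 for them. For interferon response genes all 9 arrays lay below 0.

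At 60 days, AMH and the receptors LHCGR, AMHR2 and ESR2 were higher than at 120 days. LHCGR, the receptor through which the preovulatory follicle answers luteinising hormone, was 5.76-fold higher (log2 2.53 ± 0.34 SE, n = 3, limma adjusted p = 0.00945). AMH, the anti-Müllerian hormone of growing follicles, was 6.88-fold higher (log2 2.78 ± 0.42, adjusted p = 0.0113), and its receptor AMHR2 2.06-fold (1.04 ± 0.19, adjusted p = 0.0174). ESR2, the oestrogen receptor of granulosa cells, was 1.44-fold higher (0.53 ± 0.07, adjusted p = 0.0103). Of 27 measured dominant follicle markers 6 rose, 0 fell and 21 did not pass, with the same 6 and 0 adjusted over the list alone and a median log2 of 0.56 (camera adjusted p = 0.00015, but adjusted p = 0.642 with an estimated correlation). Of 13 granulosa cell markers 2 rose (AMH and AMHR2), 0 fell and 11 did not pass, also over the list alone, with a median of 0.98 (camera adjusted p = 0.00308, adjusted p = 0.642 with an estimated correlation). INHBA, a subunit of inhibin and activin, and HSD17B1, an oestradiol-forming enzyme, had log2 values of 2.55 ± 1.05 and 1.07 ± 0.34 that did not pass (adjusted p = 0.142 and 0.0769). The 120-day spots of LHCGR, AMH, AMHR2 and ESR2 were above background on 2 of 3 arrays. On the 90-day arrays, of the same 3 sets of 120-day RNA, those of LHCGR were above background on 0 of 3. Its 120-day signal is thus near background, and the size of its change is uncertain.

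Some genes of cell division, sugar use and cholesterol synthesis were also higher at 60 days, where 869 of all 14281 genes rose and 1013 fell. Of 37 cell cycle genes 10 rose, 2 fell and 25 did not pass (11 and 2 adjusted over the list alone; median 0.57, camera adjusted p = 6.96e-06). Among them were CENPF, a centromere protein (1.48 ± 0.30, adjusted p = 0.0234), NUSAP1, of the spindle (1.07 ± 0.17, 0.0122), and TOP2A, which untangles DNA (0.73 ± 0.09, 0.00825, 120-day spots above background on 2 of 3 arrays), while MCM2, of the replicative helicase, fell by 1.12 ± 0.21 (0.0186). Of 22 glycolysis genes 3 rose, 0 fell and 19 did not pass (4 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 0.0119): SLC16A3, a lactate exporter, at 2.76 ± 0.62 (0.0293), and the phosphofructokinases PFKL at 2.15 ± 0.58 (0.0497) and PFKM at 1.30 ± 0.33 (0.0417). Of 22 cholesterol synthesis genes 2 rose, 0 fell and 20 did not pass, also over the list alone (median 0.26, camera adjusted p = 0.0349): INSIG1, a sterol sensor, at 1.03 ± 0.25 (0.0378) and DHCR7, a late enzyme of the pathway, at 0.86 ± 0.17 (0.0201, 120-day spots above background on 2 of 3 arrays). With an estimated correlation, the adjusted p of these lists was 0.642 for cell cycle and glycolysis and 0.686 for cholesterol synthesis.

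The other genes with the largest rises at 60 days were MTPN, which binds actin-capping protein (log2 3.25 ± 0.48, adjusted p = 0.0109), GPR85, an orphan receptor (3.16 ± 0.73, 0.0322), MBNL2, a splicing regulator (2.90 ± 0.51, 0.016), and TCF21, a transcription factor of mesenchyme (2.84 ± 0.34, 0.00802). They were followed by CHPF, of chondroitin synthesis (2.76 ± 0.69, 0.04), CREB3L2, a stress-sensing transcription factor (2.68 ± 0.40, 0.0113), and LTBP1, which holds latent TGF-beta in the matrix (2.66 ± 0.43, 0.0131). The 120-day spots of MTPN, GPR85, TCF21, CREB3L2 and LTBP1 were above background on 2 of 3 arrays.

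Interferon response genes were lower at 60 than at 120 days, with list medians of -0.47, -1.12 and -0.70 on the 3 arrays. Medians below 0 were not particular to 60 days. They were -0.495, -0.012 and -0.094 at 30 days and -0.081, -0.175 and -0.122 at 90 days, where the list did not pass. At 60 days all 25 measured genes had a log2 below 0, and 9 fell, 0 rose and 16 did not pass (14 fell adjusted over the list alone), with a median of -0.90. The viral RNA sensor IFIH1 fell by 2.17 ± 0.20 (adjusted p = 0.0064), HERC6, an interferon-induced ligase, by 2.11 ± 0.19 (0.00637), the chemokine CXCL10 by 1.64 ± 0.34 (0.0256), and USP18, which restrains the interferon receptor, by 0.38 ± 0.07 (0.0154). The camera adjusted p was 1.8e-07 and the fry adjusted p 0.00723, but the adjusted p was 0.642 with an estimated correlation. UBD, an interferon-induced ubiquitin-like protein outside that list, was 36.6-fold lower (log2 -5.19 ± 1.12, adjusted p = 0.027).

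Some markers of lymphocytes and neutrophils were lower at 60 days too, while those of macrophages, platelets and red blood cells did not pass as lists. Of 18 lymphocyte markers 6 fell, 0 rose and 12 did not pass (9 fell adjusted over the list alone; median -1.44, camera adjusted p = 0.000984), among them the T-cell receptor chains CD3E (log2 -3.09 ± 0.73, adjusted p = 0.0347), CD3D (-2.48 ± 0.60, 0.0377) and CD247 (-1.51 ± 0.38, 0.0408). CCR7 is among the 6, but its 60-day spots were above background on 0 of 3 arrays, so no size is given for it. GZMB, the brightest lymphocyte marker, had 0.68 ± 0.55 (0.423). Of 12 neutrophil markers 3 fell, 0 rose and 9 did not pass (4 fell adjusted over the list alone; median -0.34, camera adjusted p = 0.0164): S100A9 at -3.29 ± 0.61 (0.0179), S100A8 at -2.37 ± 0.64 (0.0494) and CAMP at -0.22 ± 0.05 (0.0407). The brightest of that list, LTF and FCGR3, had -1.46 ± 1.05 (0.366) and -3.50 ± 1.10 (0.0741). The adjusted p of both lists was 0.642 with an estimated correlation. For macrophage and monocyte markers 0 of 15 passed (median -0.50, camera adjusted p = 0.208), with the brightest, CTSS and LYZ, at -2.01 ± 0.94 (0.185) and -3.69 ± 1.34 (0.105). Of 10 red blood cell markers 1 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.973), and of 9 platelet markers 0 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.576).

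The largest falls at 60 days included other leukocyte genes. VNN2, a vanin of leukocytes, was 53.0-fold lower (log2 -5.73 ± 0.85, adjusted p = 0.0108), GIMAP4, a GTPase of lymphocytes, 17.6-fold (-4.14 ± 0.90, 0.0275), PLAC8 14.7-fold (-3.88 ± 0.94, 0.0371) and CD53, a leukocyte tetraspanin, 14.2-fold (-3.83 ± 1.02, 0.0476). GATM, of creatine synthesis, fell by 3.96 ± 0.69 (0.0156) and SAT1, which breaks down polyamines, by 3.57 ± 0.33 (0.00637). The keratins KRT19 (-4.23 ± 1.13, 0.0482), KRT8 (-3.83 ± 0.84, 0.0284) and KRT18 (-2.87 ± 0.71, 0.0385) fell as well. They were the 3 of 18 epithelial markers that passed, with 0 rising and 15 not passing (4 fell adjusted over the list alone; median -0.72, camera adjusted p = 0.00283, adjusted p = 0.642 with an estimated correlation). The epithelial median was -1.81 on replicate 2 against -0.21 and -0.32 on replicates 1 and 3.

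**Figure D3:**
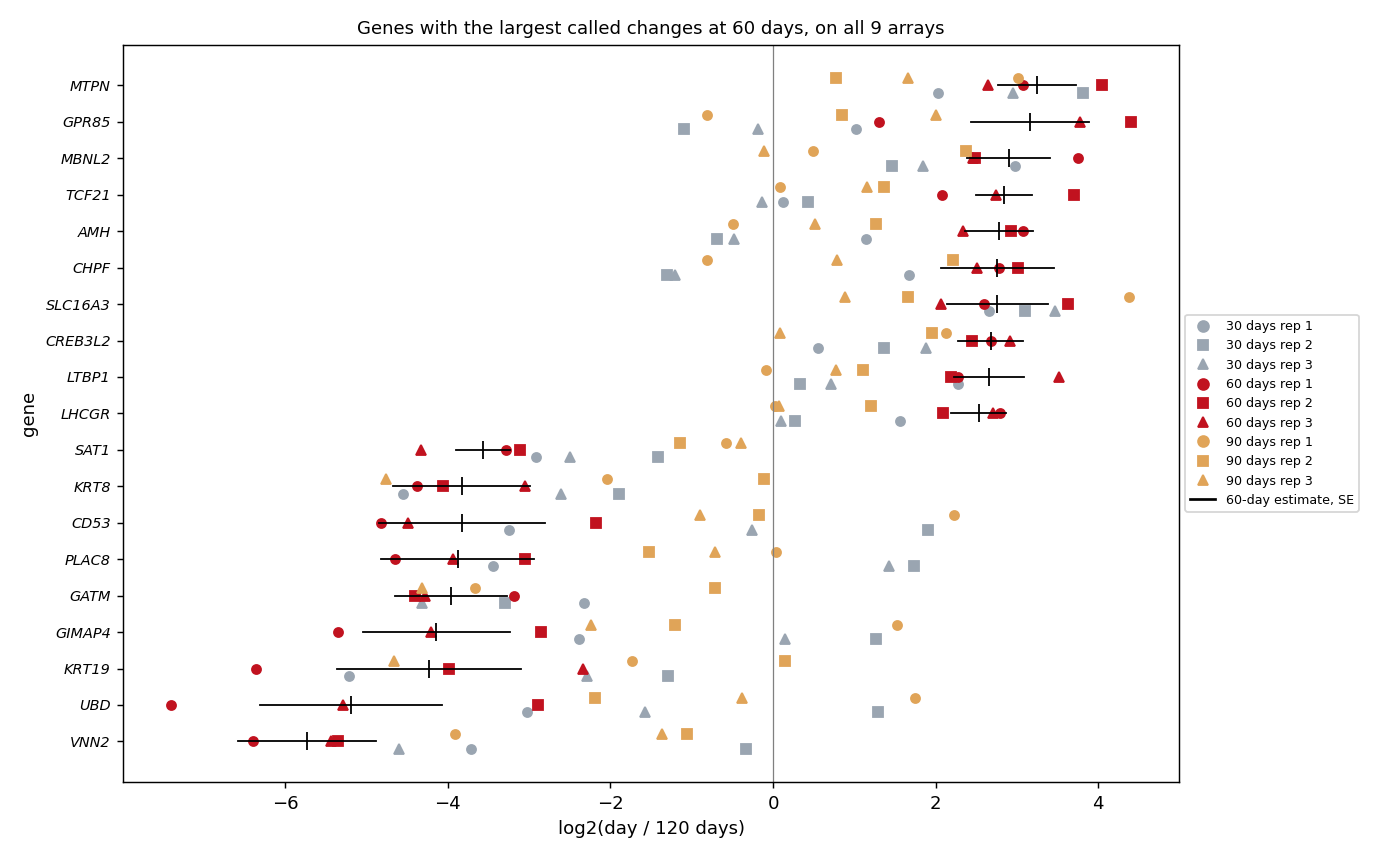
Log2 ratio of the day over 120 days of each of 19 genes on the 9 arrays (colour for the day, symbol for the replicate), with the 60-day estimate and its SE as a black tick and line. The genes are the largest changes past the threshold at 60 days, from MTPN (3.25) to VNN2 (-5.73), and for each of them the 3 arrays of 60 days lay on one side of 0.

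Of 26 immediate early response genes 2 fell, 0 rose and 24 did not pass (1 fell adjusted over the list alone; median -0.52, camera adjusted p = 0.00283, adjusted p = 0.642 with an estimated correlation). These were the kinase SGK1 (log2 -2.62 ± 0.43, adjusted p = 0.014) and FOS, of the AP-1 factor (-1.93 ± 0.49, 0.0427). MYC and DUSP1 had -1.76 ± 0.48 (0.052) and -1.65 ± 0.46 (0.0527). Of 60 cytosolic ribosomal protein genes 17 fell, 0 rose and 43 did not pass (31 fell adjusted over the list alone; median -0.47, camera adjusted p = 1.51e-11, adjusted p = 0.642 with an estimated correlation). RPS12 fell by 2.21 ± 0.29 (0.00945), RPS14 by 1.72 ± 0.23 (0.00964), RPLP1 by 1.48 ± 0.19 (0.00872) and RPL29 by 0.95 ± 0.13 (0.0103). The direction of this list depended on the normalisation, since its median was 0.17 with median centring in place of loess (camera adjusted p = 0.161). For the other 23 lists the camera adjusted p at 60 days ran from 0.051 to 0.973. Without 60 days replicate 2, 7 lists passed, and immediate early, cholesterol synthesis, glycolysis, neutrophil and epithelial genes were no longer among them. Cholesterol synthesis also lost its call without 60 days replicate 3 or 90 days replicate 3.

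The genes of oestradiol synthesis did not pass at 60 days. Of 16 steroidogenesis genes 0 passed (median 0.33, camera adjusted p = 0.197), with list medians of -0.03, 0.66 and 0.36 on replicates 1, 2 and 3. HSD3B1 had a log2 value of 1.77 ± 0.84 (adjusted p = 0.192), CYP19A1, the aromatase, 1.36 ± 1.16 (0.447), CYP11A1, the side-chain cleavage enzyme, 0.80 ± 0.71 (0.468), and STAR, the cholesterol carrier, -1.72 ± 0.70 (0.139). FSHR, the FSH receptor, had 0.98 ± 0.50 (0.224), VEGFA, an angiogenic factor, 0.61 ± 0.19 (0.0732), and IGF1 -0.07 ± 0.11 (0.701).

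By limma, 5527 of 38823 probes differed between 60 and 120 days, 2892 higher and 2635 lower, and 965 by at least 2-fold. By the 1 probe that represents each gene, 1882 genes passed, 869 higher and 1013 lower. Of the 5527 probes 2831 carry no symbol. In 52 of the 2493 genes with any probe past the threshold, probes passed in both directions. The count was 381, 3041 and 230 without replicate 1, 2 or 3 of 60 days and 3437 without 30 days replicate 3. It was 2613 with no background correction, 611 from median pixel signals, 704 without the 3 arrays of high macrophage markers (583 of them among the 5527), 1454 with the granulosa median as a covariate and 0 with only the 60-day arrays in the fit, which leaves 2 residual degrees of freedom.

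At 30 days, glycolysis genes stood higher and mitochondrial respiration genes lower than at 120 days as lists. The median of 22 glycolysis genes was 1.16 and that of 41 oxidative phosphorylation genes -0.42 (camera adjusted p = 0.000498 for both, but adjusted p = 0.829 for both with an estimated correlation, and 0.0797 for oxidative phosphorylation with median centring). The glycolysis medians were 0.21, 1.44 and 1.47 on replicates 1, 2 and 3 of 30 days and 1.46, 0.21 and -0.18 at 90 days, so the 3 highest belonged to the 3 arrays with the highest macrophage and the lowest granulosa medians. SDHC, a membrane anchor of succinate dehydrogenase, was 2.36-fold lower (log2 -1.24 ± 0.09, n = 3, limma adjusted p = 0.023, lower on 3 of 3 arrays), and SUCLG1, of succinyl-CoA ligase, 2.68-fold lower (-1.42 ± 0.14, 0.0263). The sugar enzyme PGM2 was 3.93-fold higher (1.97 ± 0.23, 0.0433). In the glycolysis list 0 of 22 genes passed (6 rose adjusted over the list alone), with the lactate exporter SLC16A3 at 3.08 ± 0.62 (0.101), PFKL at 2.66 ± 0.58 (0.114), LDHA at 1.34 ± 0.33 (0.137) and ALDOC at 1.30 ± 0.37 (0.159). In the oxidative phosphorylation list 1 fell, 0 rose and 40 did not pass (4 fell adjusted over the list alone).

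The remaining genes named at 30 days serve several functions. FBXO18, a DNA helicase (log2 1.75 ± 0.20, adjusted p = 0.0432), KAT5, a histone acetyltransferase (1.67 ± 0.22, 0.0479), TCF19 (1.49 ± 0.19, 0.0478), NPEPPS, a peptidase (1.31 ± 0.16, 0.0433), and FBXW5, of ubiquitin ligases (1.27 ± 0.16, 0.0438), rose. So did TMEM161A, DCAF8, PSKH1 and PAK1IP1, by 1.16 to 0.86 (adjusted p from 0.0328 to 0.0478). PPP1CB, a catalytic subunit of protein phosphatase 1, was lowest at -1.47 ± 0.13 (0.023), then SMS, the spermine synthase, at -1.43 ± 0.18 (0.047), FBXO9 at -1.33 ± 0.13 (0.0263), TMBIM4 at -1.23 ± 0.12 (0.0263), GOLPH3, of the Golgi, at -1.22 ± 0.14 (0.0432) and ERH at -1.20 ± 0.15 (0.0438). NBN, which senses DNA breaks, fell by 1.13 ± 0.08 (0.023) and RSRC1, of splicing, by 1.12 ± 0.13 (0.0432), with RSRC1 above background on 2 of the 3 arrays at 30 days. MOS, a kinase of the oocyte and the second brightest oocyte marker, fell by 0.77 ± 0.09 (0.0433), beside KPNA7, the brightest, at 1.26 ± 0.32 (0.145).

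Of 34 lists, 7 passed at 30 days, and 0 did with an estimated correlation, where the lowest adjusted p was 0.829, or with fry (0). Besides those above, 37 cell cycle genes had a median of 0.35 (camera adjusted p = 0.00885), 22 cholesterol synthesis genes -0.39 (0.0231), 60 ribosomal protein genes -0.12 (0.016), 15 macrophage markers 0.75 (0.0461) and 18 epithelial markers -0.61 (0.00235), with 0 genes of these lists past the threshold one by one (5 ribosomal genes fell adjusted over the list alone, 0 in the others). NUSAP1 stood at 0.62 ± 0.17 (0.156), KIF20A at 1.23 ± 0.34 (0.158), SQLE, of sterol synthesis, at -1.65 ± 0.55 (0.19) and RPS14 at -1.54 ± 0.23 (0.0639). C1QC, of complement, had 1.67 ± 0.58 (0.2), CD14 2.10 ± 0.96 (0.261), and the brightest macrophage markers CTSS and LYZ 0.16 ± 0.94 (0.935) and -0.30 ± 1.34 (0.91). KRT8 and KRT19, the brightest epithelial markers, had -3.02 ± 0.84 (0.159) and -2.93 ± 1.13 (0.217). The ribosomal median was 0.16 with median centring, and that setting also ended the calls of cell cycle and oxidative phosphorylation. The macrophage call ended without 30 days replicate 2 or 3, without any of the 60-day arrays and without 90 days replicate 2 or 3. The cholesterol synthesis medians were 0.13, -0.60 and -0.43 on replicates 1, 2 and 3, and that call ended without replicate 2 or 3. Cell cycle lost its call without replicate 3, and ribosomal proteins without replicate 1 or 3 or with the 120-day RNA as a block.

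Steroidogenic genes did not pass at 30 days, and the medians of 16 of them were -0.16, -0.20 and -0.28 on replicates 1, 2 and 3. CYP19A1 had a log2 value of -3.25 ± 1.16 (adjusted p = 0.203), from -0.82 on replicate 1 to -4.40 and -4.53 on replicates 2 and 3. CYP11A1 had -2.67 ± 0.71 (0.153), INHBA -2.14 ± 1.05 (0.284), HSD3B1 -1.87 ± 0.84 (0.258), STAR -1.5 ± 0.70 (0.268), FSHR -0.76 ± 0.50 (0.406), LHCGR 0.64 ± 0.34 (0.307), VEGFA 0.46 ± 0.19 (0.237) and IGF1 -0.07 ± 0.11 (0.74). The brightest granulosa marker, SERPINE2, had -2.64 ± 0.92 (0.2), and the list of 13 had a median of -0.76 (camera adjusted p = 0.349).

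In limma, 79 probes differed between 30 and 120 days, 37 higher and 42 lower. By the probe that represents each gene, 41 genes passed, 14 higher and 27 lower, while 49 genes had any probe past the threshold. Of the 79 probes 34 were higher and 38 lower at 60 days as well, and 0 went the opposite way. Independent calls at 30 and 60 days would share 2.76 higher and 2.85 lower probes, which leaves out the common 120-day RNA. Simulations without effects, in which the days shared only the 120-day RNA, gave a mean of 1.3 shared probes. They hold no effects to be called, so that mean is no measure for the real overlap. The count was 184 (148 higher and 36 lower), 0 and 0 without replicate 1, 2 or 3 of 30 days, 33, 30 and 0 without those of 60 days and 20, 35 and 35 without those of 90 days. It was 3218 with no background correction, 865 with the 120-day RNA as a block (244 higher and 621 lower), 347 with array weights, 120 from median pixel signals, 42 with median centring (4 higher and 38 lower), and 0 with trend and robust settings, with the granulosa median as a covariate, without the 3 arrays of high macrophage markers, or with only the 30-day arrays. The block leaves the spread between the 120-day RNAs out of the error, so its count of 865 holds for those RNAs alone. With probes averaged per gene 9 genes passed, 8 of them among the 41, including SDHC, NBN, PPP1CB and SUCLG1.

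At 90 days 1 gene differed from 120 days. PLIN3 (probe EMBV3_30376), a coat protein of lipid droplets, was 4.07-fold higher (log2 2.02 ± 0.13 SE, n = 3, limma adjusted p = 0.0221), with 2.22, 2.02 and 1.84 on replicates 1, 2 and 3, against values from 0.69 to 1.30 on the arrays of 30 and 60 days. Its ratio was thus above 0 at every day, so a dye effect of the probe was not separated from a difference from 120 days. The next smallest p-values did not pass: CCDC12 at 0.90 ± 0.09, RNF220 at 1.04 ± 0.11, H2AFJ, a histone, at 1.74 ± 0.18 and COMMD4 at 1.32 ± 0.15 (adjusted p = 0.141 for each). Below 0 lay TUBA4A, a tubulin, at -1.67 ± 0.19, MOS at -0.81 ± 0.09 and NAA35 at -0.80 ± 0.10 (each 0.141), and FRMD1 at -0.52 ± 0.07 (0.148). LRP4 (0.141) was above background on 0 of the 3 arrays in the 90-day channel, so no size is given.

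Of 34 lists, 2 passed at 90 days. The median of 15 macrophage markers was 1.03 (camera adjusted p = 0.0225, adjusted p = 0.995 with an estimated correlation), with C1QA at 1.51 ± 0.62 (0.425), C1QB at 2.06 ± 0.99 (0.475), CTSS at 0.84 ± 0.94 (0.738) and LYZ at -1.35 ± 1.34 (0.71). That of 18 epithelial markers was -0.54 (camera adjusted p = 0.0314, adjusted p = 0.995 with an estimated correlation), with KRT8 at -2.30 ± 0.84 (0.387), KRT19 at -2.08 ± 1.13 (0.516), KRT18 at -2.10 ± 0.71 (0.368) and KRT7 at -1.87 ± 0.73 (0.409). In both lists 0 genes passed one by one, also over the list alone. Without 90 days replicate 1, whose macrophage median was 2.32 and epithelial median -1.26, 0 lists passed. The steroidogenic and receptor genes had CYP19A1 at -0.50 ± 1.16 (0.882), CYP11A1 at -0.44 ± 0.71 (0.823), HSD3B1 at 0.27 ± 0.84 (0.915), STAR at -2.0 ± 0.70 (0.373), FSHR at -0.02 ± 0.50 (0.992), INHBA at -0.05 ± 1.05 (0.987), IGF1 at 0.04 ± 0.11 (0.904) and VEGFA at 0.04 ± 0.19 (0.948). LHCGR had an adjusted p of 0.639, with 120-day spots above background on 0 of these 3 arrays.

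The count at 90 days was 1 of 38823 probes in limma, with 4406 at an unadjusted p under 0.05. PLIN3 lost its call when any array other than 60 days replicate 1 was left out, with median centring, trend and robust settings, median pixel signals, the granulosa covariate, without the 3 arrays of high macrophage markers or with only the 90-day arrays, and the count rose to 763 with no background correction and to 168 with the 120-day RNA as a block.

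Between days, where a dye effect common to all arrays cancels, the smallest p-values belonged to CFD, COX4 and SDHC at 60 against 90 days, and none passed. CFD, the serine protease that starts the alternative complement pathway, was 16.3-fold lower at 60 than at 90 days (log2 -4.03 ± 0.30, n = 3 per day), with -3.25, -2.87 and -2.86 at 60 days and 1.22, 1.32 and 0.56 at 90 days, but did not pass (limma adjusted p = 0.0615). COX4, of cytochrome oxidase, stood at -1.18 ± 0.09 (adjusted p = 0.0615) and SDHC at -1.39 ± 0.13 (0.0936) in the same comparison, with no overlap between the 3 and 3 arrays, which chance gives for 10% of genes. With probes averaged per gene, CFD and COX4 passed (adjusted p = 0.0289 and 0.0337). CFD also stood at 2.35 ± 0.30 for 30 minus 60 days (0.343).

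Other genes with the smallest p-values between days did not pass either. For 60 minus 90 days these were KRCC1 at -1.22 ± 0.16 (0.189), TMSB4X, which binds actin, at -1.62 ± 0.21 (0.198), GNA11, a G-protein subunit, at 1.11 ± 0.12 (0.151), TMEM161A at 1.28 ± 0.17 (0.208), CYP4F3 at 0.99 ± 0.14, ZNF536 at 1.16 ± 0.17 and VCAN, the matrix proteoglycan versican, at 1.92 ± 0.30 (each 0.219). For 30 minus 60 days they were CALM at 0.83 ± 0.12, TMSB4X at 1.46 ± 0.21, ZBTB44 at 1.06 ± 0.16, DNAJC12 at 0.58 ± 0.09, GNA11 at -1.19 ± 0.12, CYP4F3 at -1.05 ± 0.14, ARF5 at -0.91 ± 0.13 and SLC27A1, a fatty acid carrier, at -1.22 ± 0.18 (each 0.343). ZNF536 (0.343) was above background on 0 of 3 arrays at 30 days, so no size is given. For 30 minus 90 days they were SDHC at -1.21 ± 0.13 (0.359), NBN at -0.87 ± 0.11, SDF4 at -1.35 ± 0.17 and COX4 at -0.73 ± 0.09 (each 0.391), CCDC12 at -0.91 ± 0.12 (0.411), DUS4L at 1.04 ± 0.20 (0.766), SMAD4, the common mediator of TGF-beta signals, at 0.45 ± 0.09 (0.813), and TPPP at 0.97 ± 0.19, PAX3 at 0.73 ± 0.16 and UBE2D2 at 0.94 ± 0.21 (each 0.826).

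The genes of oestradiol synthesis and its receptors did not pass between days. For 30 minus 60 days, INHBA had -4.69 ± 1.48 (0.349), CYP19A1 -4.60 ± 1.64 (0.367), HSD3B1 -3.64 ± 1.19 (0.354), CYP11A1 -3.47 ± 1.01 (0.349), LHCGR -1.88 ± 0.48 (0.343), FSHR -1.73 ± 0.71 (0.4), STAR 0.22 ± 0.99 (0.952), VEGFA -0.15 ± 0.27 (0.854), and IGF1 an adjusted p of 0.999. For 60 minus 90 days, INHBA had 2.60 ± 1.48, CYP19A1 1.85 ± 1.64 and STAR 0.28 ± 0.99, with an adjusted p of 0.347 for LHCGR and of 0.527 to 0.943 for INHBA, CYP19A1, STAR, HSD3B1, CYP11A1, FSHR, VEGFA and IGF1. For 30 minus 90 days, CYP19A1 had -2.75 ± 1.64 (0.826) and the adjusted p of all 9 genes ran from 0.826 to 0.955.

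By limma, 0 of 38823 probes passed for 30 against 90 days (2115 at an unadjusted p under 0.05, smallest adjusted p 0.359), 0 for 30 against 60 days (4747 and 0.343), 0 for 60 against 90 days (3819 and 0.0615) and 0 in the F test of any difference among the 3 days (3810 and 0.2). So the larger count at 60 than at 30 or 90 days against 120 days is not shown to be a difference between those days. Single probes passed under some settings: PHACTR2 without 30 days replicate 1 (3.28 for 30 minus 60 days and 2.73 for 30 minus 90 days), UBD with the 120-day RNA as a block (4.09 for 30 minus 60 days and -4.92 for 60 minus 90 days), CFD with array weights (-4.17 for 60 minus 90 days) and LOC784385 with median centring (-1.82 for 30 minus 90 days and -1.57 for 60 minus 90 days). PHACTR2 and LOC784385 were singled out after their values were seen.

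For 30 against 90 days 2 gene lists passed, and 0 did by fry. The median of 60 ribosomal protein genes was -0.11 (camera adjusted p = 0.000227), with RPS10 at -2.45 ± 0.43 (0.649), RPS14 at -1.31 ± 0.33 and RPS9 at -1.47 ± 0.52 (both 0.826). That of 41 oxidative phosphorylation genes was -0.25 (camera adjusted p = 0.0215), with SDHC and COX4 as above and ATP5D at -1.74 ± 0.32 (0.765). The adjusted p of both was 0.895 with an estimated correlation, and without 90 days replicate 3 neither list passed. Oxidative phosphorylation also lost its call without 30 days replicate 2. Leaving out 30 days replicate 1 or 90 days replicate 1 raised the number of lists to 8 or 9. Between 30 and 60 days 14 lists passed and between 60 and 90 days 12 did, and 0 of either with an estimated correlation.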

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

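Tests chosen only after the result was seen are those of the granulosa covariate, of the 120-day RNA and of other cells in the paragraphs on 60 days and on macrophage markers, and the list tests of 30 against 60 and of 60 against 90 days with their splits, while the other counts of splits and the epithelial tests were written first. The epithelial tests were written for arrays already named for their low epithelial ratios.

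Some lists passed between days by camera, although 0 single probes passed in limma between days (2115, 4747 and 3819 at an unadjusted p under 0.05 for 30 against 90, 30 against 60 and 60 against 90 days), and 0 lists passed by fry. For 30 minus 90 days the list median was -0.25 for oxidative phosphorylation and -0.11 for ribosomal proteins, with an adjusted p = 0.895 for both with an estimated correlation.

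For 30 minus 60 days the medians below 0 were -1.73 for granulosa cell markers, -0.93 for dominant follicle markers, -0.73 for cholesterol synthesis, -0.40 for steroidogenesis, -0.22 for cell cycle and -0.14 for endothelial markers. Those above 0 were 2.10 for macrophage markers, 1.12 for lymphocyte markers, 0.79 for interferon response, 0.68 for immediate early response, 0.64 for inflammation and NF-kB, 0.45 for neutrophil markers and 0.32 for survival genes. The ribosomal median was 0.27, and -0.10 with median centring, where endothelial markers no longer passed (camera adjusted p = 0.062). The adjusted p of these lists was 0.421 to 0.571 with an estimated correlation.

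For 60 minus 90 days the medians above 0 were 1.11 for granulosa cell markers, 1.02 for dominant follicle markers, 0.51 for cholesterol synthesis, 0.28 for cell cycle and 0.28 for TGF-beta family signalling. Those below 0 were -2.13 for macrophage markers, -1.47 for lymphocyte markers, -0.85 for interferon response, -0.56 for inflammation and NF-kB, -0.44 for ribosomal proteins, -0.34 for neutrophil markers and -0.29 for immediate early response. With median centring the ribosomal median was -0.16, and immediate early response no longer passed (camera adjusted p = 0.0774). The adjusted p of these lists was 0.387 to 0.532 with an estimated correlation.

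Between arrays with the same 120-day RNA (sets A, B and C), interferon response kept its sign in all 3 sets, with 0.28, 1.47 and 0.68 for 30 minus 60 days and -0.44, -1.49 and -0.57 for 60 minus 90 days. Granulosa markers did so too, with -0.24, -2.15 and -2.42 and then 0.29, 1.95 and 0.30. The sign was not kept in all 3 sets for macrophage markers (-0.25, 2.91 and 4.03), survival genes (-0.07, 0.61 and 0.52) and steroidogenesis (0, -0.64 and -0.81) at 30 minus 60 days. The same held for immediate early response (-0.60, -0.77 and 0.23) and cell cycle (0.15, -0.02 and 0.84) at 60 minus 90 days, and for oxidative phosphorylation (0.06, -0.16 and -0.44) at 30 minus 90 days. Each set holds 1 array per day, too few for a test within it.

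More probes differed from 120 days at 60 days (5527) than at 30 or 90 days (79 and 1), a contrast between days that was itself not shown by any probe in the main fit. Of the 84 choices of 3 of the 9 arrays, 1, the real one, gave as many as 5527 probes, and the highest of the others gave 4075. Each day holds 1 array of each 120-day RNA set, which most of those choices do not keep. In addition, 60 days was picked as the largest of 3 days. So that share does not exclude chance for the count. The spread between the arrays of a day was widest at 90 days and not at 60 days (median SD 0.162, 0.173 and 0.188 at 30, 60 and 90 days). The fit pools it and gives each day the same median SE of 0.117, so unequal spread can change the counts. Its part in this contrast was not tested. With the granulosa median as a covariate 1454 probes passed at 60 days, against 0 at 30 and 0 at 90 days, which met the rule against granulosa share as the whole cause. That median comes from the same arrays and was above 0 on every array of 60 days. An imprecise correction can therefore leave calls, and granulosa share is not excluded. A change of the granulosa cells between 60 and 120 days may be involved, and differences between cows remain open and untested.

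The granulosa medians were low and the macrophage medians high on 30 days replicates 2 and 3 and 90 days replicate 1. The 120-day RNA of those arrays is argued against, because the lowest granulosa median among the other arrays with the same RNAs was 0.15. A lower granulosa share that raises all other types alike stays open, because the macrophage median exceeded the lymphocyte median by 1.77, 1.78 and 0.88 on arrays picked for a high macrophage median, and by up to 1.12 on the other arrays. Lymphocyte and platelet medians were above 0 on all 3 arrays. Theca and stroma medians (-0.07, -0.34 and -0.06) and endothelial medians (-0.11, -0.18 and 0.04) were not raised alike. Those 2 lists are dim (median A 8.84 and 8.01, against 10.35 for macrophage markers), which limits what their ratios can show. Macrophage RNA in these samples cannot be told apart from a change in the expression of those genes, since the 14 of 15 macrophage markers above 0 on all 3 arrays only restate how these arrays were picked, and of the brightest markers CTSS had 1.89, 1.77 and 1.73 but LYZ had -0.73 on 30 days replicate 3 and -0.87 on 90 days replicate 1. A sort of the cells is not given in the sources used here, and a biological difference between the follicles of the same day was not tested.

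Epithelial medians were low on replicate 2 of 30 and 60 days and replicate 1 of 90 days, the arrays of 120-day set B. Their Cy3 medians of epithelial genes were 9.28, 9.42 and 9.33, the lowest of them 0.17 above the highest of the other arrays (9.11). This is what epithelial RNA in the 120-day RNA they share would give. But the arrays were named for low ratios of Cy5 over Cy3, which favours high Cy3 medians. The Cy3 test is therefore partly set by that choice. By the rule written first, at least 1 Cy5 median at or above the middle of the others counts against less epithelial RNA in their samples. This was met, since the highest of their Cy5 medians (8.01, 7.89 and 8.09) lay 0.13 above that middle. All 3 lay within the range of the others, from 7.73 to 8.14. The margin is small beside that range, a limit the rule did not set, so a smaller part of less epithelial RNA in the samples is not excluded. KRT19 and KRT8, the brightest members, had -4.23 and -3.83 at 60 days, and no biological explanation was tested, since the design groups no 120-day samples.

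Chance is also not excluded for the counts at 30 and 90 days, nor for the lists of the 3 days against 120 days. At 30 days 17 of 84 choices of 3 arrays gave as many as 79 probes, the highest of the others being the 60-day arrays with 5527, and at 90 days 37 gave as many as 1, with the same highest other. The arrays that share a 120-day RNA gave 2740 probes for set B, 482 for set C and 49 for set A, so sets B and C exceeded the 79 and 1 probes of 30 and 90 days in the same form of fit. The 3 arrays of high macrophage markers gave 2490 probes and 11 lists. With the 120-day RNA as a block, another form of fit that was not run on the other choices of arrays, 30 and 90 days had 865 and 168 probes. For gene lists, 32 of 84 choices gave as many as 7 lists (30 days), 5 gave as many as 11 (60 days) and 80 gave as many as 2 (90 days), with 14 lists as the highest of the others each time. For any difference among the 3 days the real count is 0, which any split reaches (100 of 100), so that number says nothing about chance. The highest count among those splits was 711.

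The 10 splits of 6 arrays are too few for a share under 0.05. The real and the highest other counts were 0 and 528 probes for 30 against 90 days, 0 and 0 for 30 against 60 days, 0 and 1 for 60 against 90 days, with 2 and 11 lists for 30 against 90 days, 14 and 15 for 30 against 60 days, and 12 and 10 for 60 against 90 days. As many lists as the real split came from 10, 3 and 1 of the 10 splits in that order. The split with 528 probes set 30 days replicate 1 and 90 days replicates 2 and 3 against 30 days replicates 2 and 3 and 90 days replicate 1. The latter are the 3 arrays of high macrophage and low granulosa medians, so the split follows a grouping other than the day. It also put the arrays of set A against those of set B, with an array of set C on each side. A difference between the Cy3 RNAs of sets A and B was therefore not separated from a structure of the samples.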

How the results depend on the processing

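Tests chosen only after the data were seen are those with the 120-day RNA as a block, the granulosa covariate, the filter from the median and MAD, median pixel signals and without the 3 arrays of high macrophage markers, and the median centring of single list medians. The probe counts are given in the order of 30, 60 and 90 days against 120 days (79, 5527 and 1 as reported). They were 3218, 2613 and 763 with no background correction, 865, 6584 and 168 with the 120-day RNA as a block, and 3021, 3771 and 1041 at an unadjusted p under 0.05 with a 1.5-fold change. They were 120, 611 and 0 from median pixel signals, 42, 4626 and 0 with median centring, 347, 7363 and 1 with array weights, and 0, 5175 and 0 with trend and robust settings. They were 0, 1697 and 0 with the replicate number as a block, 0, 1454 and 0 with the granulosa covariate, 0, 704 and 0 without the 3 arrays of high macrophage markers, and 0, 0 and 0 with only the arrays compared, where 2 residual degrees of freedom are left. Leaving out 1 array gave 0 to 184, 230 to 6457 and 0 to 1. Of the 5527 probes, 1289 were among the 1454 and 583 among the 704. Against 120 days, the 120-day RNA as a block leaves the spread between those RNAs out of the error. Its higher counts are therefore no sign of robustness. Deviations of arrays with the same number correlated over probes at 0.34, 0.51 and 0.382 between 30 and 60 days, where the number is also the 120-day RNA set, and from -0.688 to 0.187 between those days and 90 days, so the number was not used as a pair. With no filter the counts were 66, 6629 and 1, and with the filter from the median and MAD 77, 5859 and 1. Aquantile changes only the mean brightness here, so it tests nothing. Between days limma's 0 became 1 with median centring for 30 against 90 days, 60 against 90 days and the F test, 1 with the 120-day RNA as a block for 30 against 60 days, 60 against 90 days and the F test, and 1 with array weights for 60 against 90 days. Leaving out 1 array gave 0 to 1 for 30 against 90 days, 30 against 60 days and the F test, and at an unadjusted p under 0.05 with a 1.5-fold change 928, 1335, 1548 and 1528 probes passed for 30 against 90, 30 against 60, 60 against 90 days and the F test. With probes averaged per gene the counts of genes were 9 in place of 41 at 30 days, 1362 in place of 1882 at 60 days (1265 shared), 2 in place of 1 at 90 days and 2 in place of 0 for 60 against 90 days. The 7, 11, 2 and 2 lists for 30, 60 and 90 against 120 days and 30 against 90 days became 0, 0, 0 and 0 with an estimated correlation, 0, 2, 0 and 0 by fry, 4, 10, 6 and 5 with median centring, 7, 11, 4 and 4 with the 120-day RNA as a block, and 3 to 9, 7 to 13, 0 to 8 and 1 to 9 when 1 array was left out. The median of the ribosomal list changed sign with median centring, to 0.16 at 30 days, 0.17 at 60 days and -0.10 for 30 minus 60 days. Of 48 named genes past the threshold at 60 days, 44 passed with the 120-day RNA as a block, 43 with array weights, 42 with trend and robust settings, 38 with probes averaged, 32 with median centring, 29 with no background correction, 25 with the replicate number as a block, 22 from median pixel signals, 20 without the 3 arrays, 19 with the granulosa covariate, 4 whichever array was left out and 0 with only the arrays compared. PLIN3 had an adjusted p from 0.00562 to 0.716 over the alternatives. Except for the arrays and degrees of freedom that some settings remove, the cause was not tested. Fits to the deposited table or with slide position were not run. Signal over background limits what can be read on 30 days replicate 1 (29.8% of probes above background in Cy5) and 60 days replicate 3 (20.9% in Cy3).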

Other observations

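The tests in this part that were chosen only after the data were seen are the comparison of the deposited value table with the arrays and the overlap between days.

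Extracellular matrix genes did not pass as a list at 60 days (camera adjusted p = 0.121), though 5 of 36 rose and 1 fell (5 and 3 adjusted over the list alone), with a median log2 of 0.16 and a mean of -0.05. The collagens COL4A1 at 2.07 ± 0.52 (limma adjusted p = 0.0406) and COL4A3 at 0.70 (0.0139) and the laminin LAMB2 at 2.11 ± 0.39 (0.0187), which occur in basement membranes, were among those that rose. TIMP1, an inhibitor of matrix proteases, fell by 3.56 ± 0.78 (0.0281). COL4A2 also passed, but its 120-day spots were above background on 0 of 3 arrays, so no size is given.

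Genes of the response to luteinising hormone went both ways at 60 days. Versican (VCAN) rose by 2.16 ± 0.21 (adjusted p = 0.00648), while PTX3, of the cumulus matrix, fell by 1.64 ± 0.22 (0.00981) and the prostaglandin receptor PTGER4 by 2.14 ± 0.44 (0.0238), with 3 of 27 rising and 3 falling (camera adjusted p = 0.389). Among antioxidant genes SOD2 fell by 1.95 ± 0.37 (0.0186) and GPX4 by 1.49 ± 0.36 (0.0368), and GCLC rose by 0.78 (0.0223), with a camera adjusted p of 0.501 over 31 genes. The glucocorticoid receptor NR3C1 rose by 2.17 ± 0.42 (0.0201) and the leptin receptor LEPR by 0.31 ± 0.05 (0.0164). Their list of 14 receptors had a camera adjusted p of 0.051 and a fry adjusted p of 0.0351.

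The estimates of 30 and 60 days correlated at 0.522 over 38823 probes, which are not independent replicates, against 0.368 in 20 simulations that shared only the 120-day RNA. For 30 and 90 days r was 0.641 (0.368 simulated) and for 60 and 90 days 0.497 (0.366 simulated). Their calls overlapped by 34 higher and 38 lower probes at 30 and 60 days, where independent calls would share 2.76 and 2.85. The mean of 1.3 in those simulations, which hold no effects to be called, is no measure for that overlap. A dye effect, which every array shares, and a difference from 120 days common to all days were not separated, since no array has the dyes exchanged.

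The columns of the deposited value table had medians of -0.005, 0.026 and -0.007 for replicates 1, 2 and 3 of 30 days, -0.021, 0.007 and -0.004 of 60 days, and 0.002, 0.013 and 0 of 90 days. Of the 9 columns 0 were matched best by the log2 ratio of their own array, 5 by the ratio of another array and 4 by a difference between channels of 2 arrays, with best r from 0.94 to 0.982 over 10949 probes. With the own array's ratio, r ran from -0.848 to 0.799. In the table's order, each of 8 columns after the first was matched best by a difference that starts from the channel at which that of the column before it ends. These channels were of the 90-day arrays and of replicates 1 and 2 of 60 days, in the order 90 and then 60 days. How these values were made is not given in the sources used here.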
